A study of Gallus gallus with 54 samples.

How the data were processed

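RNA from whole chick retina was sequenced in 54 libraries, which fall into 7 conditions at 2 times, 4 h and 24 h. The conditions were untreated birds, form-deprivation myopia (FDM, in which a translucent diffuser over the eye makes it grow too long), FDM with 1 of 4 injected drugs, and recovery, in which a diffuser worn for 3 days was taken off. The drugs were atropine and pirenzepine (antagonists of muscarinic acetylcholine receptors), ADTN (a dopamine receptor agonist) and TPMPA (an antagonist of GABA-C receptors). Each group held 4 libraries, except recovery at 4 h and untreated at 24 h, which held 3. Per the labels, the birds were male White Leghorn chicks raised on a cycle with 12 h of light for 6 days before the experiment. They were 7 days old at collection for the 4 h groups and 8 days old for the 24 h groups. Birds of the 24 h drug groups received a repeat injection 4 h before collection. The data used here include no group injected with vehicle alone, so drug and injection form a single contrast with FDM. Whether each library came from a different bird is not given in the sources used here. P-values therefore measure the spread between samples.

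Total RNA (RNA integrity number above 7.0) was extracted with Trizol, and stranded libraries were read in pairs with a 75-cycle kit on a NextSeq 500. The authors' processing notes name Trimmomatic 0.36, HISAT2 2.1, HOMER, edgeR, limma and the genome build galGal5. The role and order of each tool, and any filter on reads or duplicates, are not given in the sources used here. The deposited values are raw counts, 1 per transcript of the Ensembl annotation and library, in 38118 transcript entries; transcripts of a gene share reads. Deposited transcript lengths and coordinates, both in bases, were taken as given (a unit other than counts, used only to place genes and to compute counts per base).

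The entries carry 24881 gene identifiers. To test each gene once, the transcript with the largest total count over all libraries was taken for each gene name, which left 24599 entries. Entries without a symbol made up 39.5% of the table and 12.6% of the counts, and they are named by their Ensembl identifier. Low counts were removed with filterByExpr of edgeR (minimum count 10, minimum total 15), which left 15746 genes. Total counts over those chosen transcripts ran from 7.4 to 24.8 M per library, with a median of 14.8 M. The densest genes held up to 15.8 counts per base. Among the 100 densest genes counts rose with depth with a slope of 0.466 on the log scale, against 1.16 for 100 genes of middle density. Folds of the most abundant transcripts are therefore compressed, and none of the 10 densest genes is singled out here.

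Counts were normalised by TMM and fitted with edgeR 4.0.16 (robust quasi-likelihood, glmQLFit and glmQLFTest) in R 4.3.3. A single model held all 54 libraries with a mean for each of the 14 groups. P-values were adjusted by the Benjamini-Hochberg method over the 15746 genes, with a threshold of 0.05 and no minimum fold; all such p-values are two-sided. Every adjusted p given for a gene comes from that quasi-likelihood test unless another tool is named. CPM values (counts scaled to library size) are TMM-normalised and given as mean ± SD over the libraries of a group. Log2 fold changes are given ± SE, where the SE is the size of the log2 change divided by the square root of the quasi-likelihood F. Groups hold 4 libraries unless a different n is stated.

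Main comparisons, at each time, were FDM with untreated, each drug group with FDM, and recovery with untreated. Secondary comparisons were recovery with FDM, atropine with pirenzepine, and untreated at 24 h with untreated at 4 h. For each main pair of groups, the difference between its 24 h and 4 h changes was also tested. Comparisons, lists and tests were chosen before the data were examined, except where a test is said to have been chosen afterwards. Genes were named by a rule. In each main comparison it took the 10 largest rises and the 10 largest falls among genes past the threshold with a symbol, a mean of at least 2 CPM over the 54 libraries and no overlap between the libraries of both groups. It took 5 and 5 in each secondary comparison. It added up to 4 examples from each list and 7 genes followed in every main comparison whatever their result: EGR1, VIP, GCG, BMP2, NTS, UTS2B and TH. The text gives a part of the genes so named, and a few results are not reported. For 4 libraries against 4, complete separation arises by chance in 1 of 35 splits. The rule required it of the largest rises and falls, so it lends those genes no further support.

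Gene lists were tested with camera of limma 3.58.1 (preset correlation 0.01, lists of at least 4 measured members), adjusted over the 336 tests of 28 lists in 12 main comparisons. Counts of members "adjusted over the list alone" use Benjamini-Hochberg over the list's own members. As alternatives, camera was run with an estimated correlation and fry was run. The lists, with the number of members tested, were immediate early genes (34), retinal peptides and growth signals linked to eye growth (20), BMP and TGF-beta signalling (20), the dopamine system (19), the cholinergic system (21), the GABA and glycine system (32), circadian clock and melatonin (29), phototransduction (34), retinoic acid (19), heat shock and protein folding (32), Mueller and reactive glia (28), microglia and leukocytes (29), cytokines and NF-kB (27), interferon-stimulated genes (29), hypoxia and glycolysis (33), oxidative phosphorylation (61), ribosomal proteins (62), cholesterol and lipid synthesis (26), ganglion cells (19), bipolar cells (17), amacrine and horizontal cells (18), lens (12), retinal pigment epithelium and melanocytes (25), red blood cells (9), blood vessels and pecten (22), connective tissue (22), oligodendrocytes and myelin (18), and ciliary body and iris (18).

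Libraries were examined for structure other than the groups. A score of 7 small structural RNAs, such as RNase P RNA and U1 (mean log2 CPM), split the libraries into 20 with high values (2.14 to 3.63) and 34 with low values (-1.13 to 0.926), with none between. The labels name no batch. High values were found in 1 to 3 libraries of 10 groups and in none of the atropine groups, pirenzepine at 4 h and TPMPA at 24 h. The score of the blood vessel and pecten list (mean log2 CPM of its members) also varied between and within groups. Both were used as added terms, chosen after seeing the data, as was log2 total count. The labels do not say that libraries with equal replicate numbers belong together, so the replicate number as a block was an alternative. None of 78 pairs of libraries within groups held identical counts.

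The model was tested on simulated data built from the observed counts. For FDM against untreated at 4 h, 65.7% of 1.5-fold, 88.1% of 2-fold and 93.9% of 4-fold changes were recovered. At 24 h the shares were 53.7%, 82.1% and 95.5%. False calls made up 2.19% of calls at 4 h and 3.75% at 24 h. With camera, a list of 30 genes shifted by 0.5 log2 was called and 0 of 50 unshifted lists were. These rates were not checked against states real libraries share.

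Alternatives were DESeq2 1.42.0, limma voom, RLE size factors, no filter on low counts, every transcript entry tested separately, a fit of only the groups compared, the replicate block, and each library left out in turn. Alternatives added after seeing the data were the terms above, fits within the low or within the high small-RNA libraries where both groups kept at least 2, and untreated 4 h libraries 1 and 3 left out together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3). Reads were not used here, and no gene was left out other than by the filters above.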

Results

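Transcript counts were measured in whole retina from 54 libraries in 14 groups: 7 conditions, each at 4 h and 24 h. Total counts per library over the transcripts used ran from 7.4 to 24.8 M. Group means at 4 h were 16.8 ± 4.36 M for untreated, 12 ± 3.35 for form-deprivation myopia (FDM), 17.9 ± 4.61 for FDM with atropine, 14.5 ± 4.74 with pirenzepine, 16.2 ± 3.07 with ADTN, 17.5 ± 4.27 with TPMPA and 16.1 ± 1.64 for recovery (SD, n = 4, recovery n = 3). At 24 h, in the same order, they were 13.3 ± 2.13 (n = 3), 16 ± 1.43, 16.2 ± 5.77, 13.4 ± 1.57, 15.2 ± 3.56, 12.3 ± 1.48 and 15.7 ± 1.37 M. The largest component of variation between libraries (19.4%) followed the level of blood vessel and pecten genes; the pecten is the vascular structure that projects into the avian eye. The next component (8.07%) followed the level of small structural RNAs. Both vary within groups, so values with either as a term, or within the low or the high small-RNA libraries, stand beside the counts they change. Gene positions are in galGal5.

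The comparison of FDM with untreated retina at 4 h asks what the loss of form vision does to the retina on its first day. Genes that respond within minutes to neuronal activity were lower under the diffuser. DUSP4, a phosphatase that restrains MAP kinases (ENSGALG00000011419, chromosome 4, 49691811 to 49696013), fell by 1.43 ± 0.24 on the log2 scale, from 13.6 ± 2.52 to 5.01 ± 1.28 CPM (adjusted p = 0.00134). MAFF, a small Maf transcription factor (chromosome 1, 51010583 to 51013540), fell by 1.32 ± 0.2, from 48.8 ± 21.3 to 19.6 ± 1.3 CPM (adjusted p = 0.000524). For both genes every FDM library lay below every untreated library, and both calls held without any single library. For the largest rises and falls, here and below, such a lack of overlap was a condition of naming them. FOS, a transcription factor induced by depolarisation (ENSGALG00000028037, chromosome 5, 38264804 to 38267713), fell by 1.68 ± 0.39 to 8.93 ± 1.72 CPM (adjusted p = 0.048), a call lost without any of untreated libraries 1 to 3 or FDM libraries 1 to 4 (adjusted p up to 0.296).

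In all, 27 of 15746 genes fell and none rose. Of 34 immediate early genes 6 fell (10 adjusted over the list alone), among them NR4A1 (adjusted p up to 0.303 without untreated libraries 1 or 3 or FDM libraries 2, 3 or 4), DUSP6 and BDNF (up to 0.195 without untreated libraries 1, 2 or 3 or FDM libraries 3 or 4). The list was lower with adjusted p = 6.19e-15, and adjusted p = 0.00723 with an estimated correlation. EGR1, a marker of amacrine cell activity in this model (ENSGALG00000007669, chromosome 13, 18348955 to 18351756), stood at 21.7 ± 1.61 CPM against 55.6 ± 12.8 in untreated retina without passing the test over all genes (adjusted p = 0.318). The peptide transmitter VIP stood at 17 ± 3.11 against 31.7 ± 7.96 CPM (adjusted p = 0.102), and the urotensin peptide UTS2B at 3.63 ± 0.83 against 8.53 ± 1.88 (adjusted p = 0.144). CHAC1, a stress-induced enzyme of glutathione breakdown, fell by 4.30 ± 0.73 (adjusted p = 0.00247), from 40.4 ± 40.2 CPM, a mean carried by untreated libraries 1 and 3; without FDM library 3 the adjusted p was 0.0511. Ribosomal proteins (61 of 62 with a positive change, median 0.2) and oxidative phosphorylation were higher as lists with 0 members past the threshold. Their adjusted p were 2.7e-15 and 5.18e-10, or 0.553 and 0.543 with an estimated correlation. No list test fitted total count, lower in FDM (mean 12 against 16.8 M). Phototransduction genes were higher as a list (adjusted p = 1.32e-07, or 0.409 with an estimated correlation), with 0 of 34 past the threshold and 2 adjusted over the list alone. The count of 27 became 4, 6 and 73 without untreated libraries 1, 3 and 4, and 49, 7, 3 and 5 without FDM libraries 1 to 4; without untreated libraries 1 and 3 together it was 0. It was 39 with the small-RNA batch as a term, 48 within the low small-RNA libraries, 26 with the vessel score, 8 with total count as a covariate, 4 with only the groups compared in the fit, 63 by DESeq2 and 2 by limma voom.

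**Figure D1:**
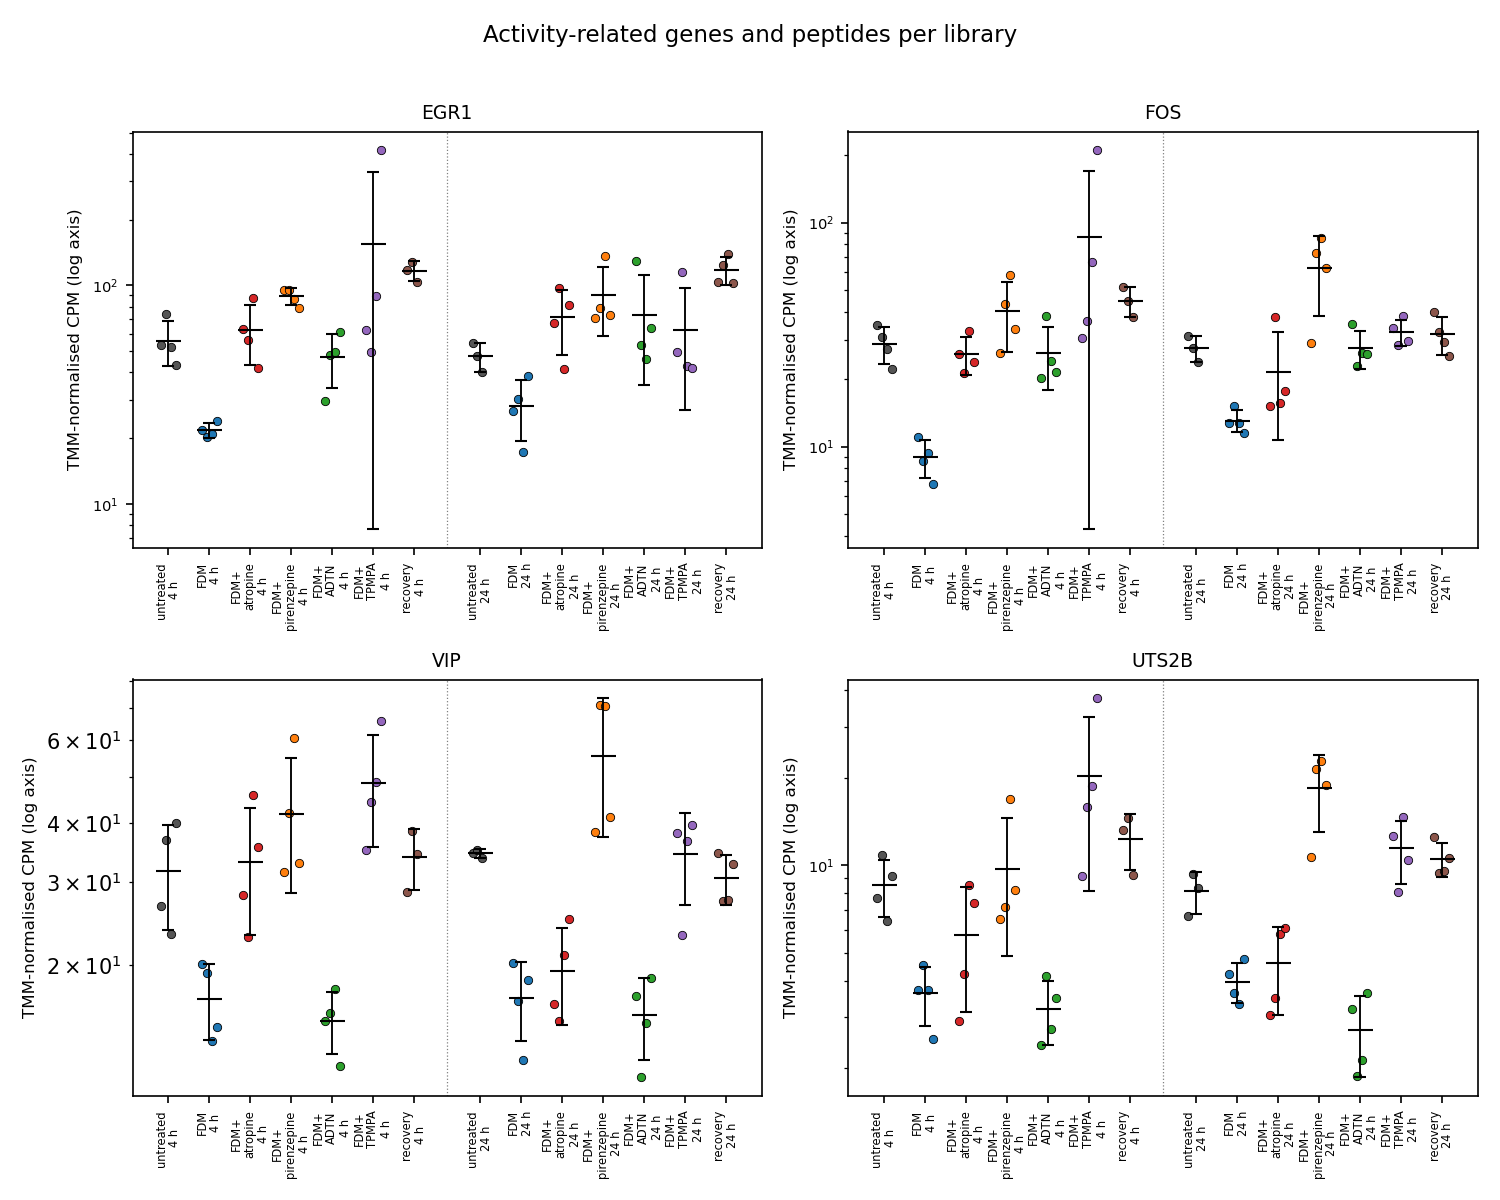
EGR1, FOS, VIP and UTS2B in each of the 14 groups. Each point is a library, the vertical axis is TMM-normalised CPM on a log scale, dashes are means and bars are SD; the 4 FDM libraries at 4 h hold 6.8 to 11 CPM of FOS, below the 4 untreated libraries.

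Atropine, given to birds wearing diffusers, was compared with FDM alone to show which retinal transcripts follow this muscarinic antagonist. At 4 h, several genes of cytokine and STAT signalling rose. SOCS3, a feedback inhibitor of that pathway (ENSGALG00000027786, chromosome 18, 9931036 to 9933083), rose from 0.781 ± 0.537 to 23.1 ± 6.92 CPM (log2 4.82 ± 0.95, adjusted p = 0.00406). STAT3, its transcription factor (ENSGALG00000003267, chromosome 27, 5319501 to 5330786), rose from 196 ± 7.6 to 463 ± 34.2 CPM (1.24 ± 0.18, adjusted p = 6.57e-05). The cell-surface proteoglycan SDC1 (ENSGALG00000016480, chromosome 3, 102005547 to 102025143) rose from 1.88 ± 0.495 to 49.8 ± 7.23 CPM (4.76 ± 0.8, adjusted p = 0.00055), and GFAP, the intermediate filament of reactive glia, from 11.3 ± 3.87 to 46.3 ± 4.35 (2.02 ± 0.41, adjusted p = 0.00505). IFITM5, of the interferon-induced transmembrane family (ENSGALG00000004239, chromosome 5, 1556571 to 1558140), rose from 6.01 ± 0.296 to 31.7 ± 3.18 CPM (2.40 ± 0.28, adjusted p = 5.05e-07). SFRP1, a secreted Wnt antagonist, fell by 0.71 ± 0.11 to 239 ± 10.7 CPM (adjusted p = 7.01e-05), and AOX1, an aldehyde oxidase, fell by 1.39 ± 0.25 to 26.1 ± 3.75 (adjusted p = 0.00111). None of these 7 genes overlapped between the 4 and 4 libraries.

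Atropine raised 147 genes at 4 h and lowered 38. Among cytokine and NF-kB genes 7 of 27 rose (13 adjusted over the list alone, adjusted p = 3.51e-14, or 0.05 with an estimated correlation). Among interferon-stimulated genes 5 of 29 rose (19 adjusted over the list alone, adjusted p = 2.4e-20, or 0.0948 with an estimated correlation). Vessel scores were 2.72 ± 1.23 with atropine and 1.4 ± 0.833 in FDM, and leukocyte scores were 2.49, 1.83, 1.21 and 1.51 in atropine libraries 1 to 4 and 0.977 to 1.37 in FDM. In the glial list 3 of 28 rose and 2 fell, among them the water channel AQP4 (adjusted p = 0.00717, or 0.437 with an estimated correlation). Among growth-related peptides VIP and SST rose, IGF2 fell by 0.79 ± 0.17, and the list of 20 was higher (5 up and 1 down adjusted over the list alone, adjusted p = 0.0115, or 0.362 with an estimated correlation). FOS rose alone among immediate early genes (8 adjusted over the list alone, adjusted p = 0.000154, or 0.361 with an estimated correlation). Its call was lost without any of FDM libraries 2 to 4 or atropine libraries 1 and 3 (adjusted p up to 0.137), and that of VIP without FDM libraries 3 or 4 or atropine library 3 (adjusted p up to 0.119). Phototransduction genes were lower as a list: ARR3 and RGS9 fell (11 adjusted over the list alone, adjusted p = 2.85e-07, or 0.431 with an estimated correlation). In FDM this list lay above untreated at 4 h, so falls with any drug were not told apart from high FDM values. The count of 185 was 96, 107 and 91 without FDM libraries 2, 3 and 4 and 104 without atropine library 1. All atropine libraries were low in small RNAs; the count was 257 with the batch as a term, 247 within the low libraries and 130 with the vessel score.

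Pirenzepine, the other muscarinic antagonist, raised several genes of neuronal activity and of STAT signalling at 4 h. EGR1 rose from 21.7 ± 1.61 to 89.1 ± 7.82 CPM (log2 2.04 ± 0.44, adjusted p = 0.00611), and FOS from 8.93 ± 1.72 to 40.4 ± 14 (2.17 ± 0.39, adjusted p = 0.000786). The peptides VIP (ENSGALG00000013604, chromosome 3, 49646763 to 49653486) and SST, somatostatin, rose to 41.6 ± 13.3 CPM (1.30 ± 0.23, adjusted p = 0.000767) and 7.26 ± 3.8 CPM (3.52 ± 0.56, adjusted p = 0.000146). STAT3 rose to 524 ± 103 CPM (1.42 ± 0.18, adjusted p = 4.28e-06), IFITM5 to 30.4 ± 10.1 (2.34 ± 0.28, adjusted p = 1.05e-06), and OCA2, a melanosome transporter, to 119 ± 24.8 (1.44 ± 0.19, adjusted p = 4.28e-06). The calls of these 7 genes held without any single library, with no overlap between the 4 and 4 libraries.

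In all 219 genes rose and 110 fell under pirenzepine at 4 h. Among growth-related peptides 6 of 20 rose (7 up and 1 down adjusted over the list alone, adjusted p = 2.43e-05, adjusted p = 0.0735 with an estimated correlation), and 5 of 34 immediate early genes rose (7 adjusted over the list alone, adjusted p = 0.000314, adjusted p = 0.362 with an estimated correlation). Cytokine and NF-kB genes rose in 8 of 27 (10 adjusted over the list alone, adjusted p = 7.21e-11, adjusted p = 0.0948 with an estimated correlation) and interferon-stimulated genes in 4 of 29 (12 adjusted over the list alone, adjusted p = 8.06e-09, adjusted p = 0.398 with an estimated correlation). GFAP, SOX2, STAT3 and SOCS3 rose among 28 glial genes (6 up and 1 down adjusted over the list alone, adjusted p = 0.0253, or 0.538 with an estimated correlation). Of 34 phototransduction genes 3 fell and CNGB1 rose (1 up and 8 down adjusted over the list alone, list lower with adjusted p = 4.13e-05, or 0.543 with an estimated correlation). The count of 329 was 181 and 177 without FDM libraries 2 and 4, and 142 without pirenzepine library 2. All pirenzepine libraries at 4 h were low in small RNAs; the count was 417 with the batch as a term, 164 within the low libraries and 383 with the vessel score.

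Atropine and pirenzepine share the muscarinic receptors as target and were compared at equal times. No gene differed between them at 4 h by edgeR (smallest adjusted p = 0.198), 1208 genes had an unadjusted p under 0.05, DESeq2 called 5 genes and limma voom 0; without pirenzepine library 1 edgeR called 4. Of the 117 genes past the threshold against FDM with both drugs, the 95% interval of the difference held 0 for 115. The intervals reached 0.13 to 1.43 log2 units to either side of the difference (median 0.47). For STAT3 atropine minus pirenzepine was -0.18 (-0.54 to 0.19), for IFITM5 0.06 (-0.46 to 0.58), for FOS -0.64 (-1.36 to 0.08) and for VIP -0.33 (-0.79 to 0.12). Differences inside those limits were not detectable here. At 24 h, 31 genes differed, 28 of them lower with atropine. VIP stood at 19.4 ± 4.48 CPM with atropine and 55.3 ± 18 with pirenzepine (log2 -1.51 ± 0.23, adjusted p = 0.000747), and UTS2B (ENSGALG00000007222, chromosome 9, 13751029 to 13757813) at 4.61 ± 1.54 and 18.4 ± 5.41 CPM (-1.99 ± 0.33, adjusted p = 0.00194), both with no overlap between the 4 and 4 libraries and without loss when any single library was left out. Of 34 immediate early genes 3 were lower with atropine (5 adjusted over the list alone), as were 3 of 20 growth-related peptides (4 adjusted over the list alone); lists were not tested in this comparison. For 11 of 13 genes past the threshold with both drugs, chosen in the same way and with the same limit, the interval held 0, as for SDC1 (-1.25, from -2.53 to 0.02). The count of 31 was 10, 8 and 12 without atropine libraries 1, 3 and 4, and 48, 10 and 14 without pirenzepine libraries 1 to 3. It was 21 with the small-RNA batch as a term, 17 within the low libraries and 38 with the vessel score.

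ADTN, a dopamine receptor agonist, was compared with FDM to find retinal transcripts that change with its injection. At 4 h it lowered some genes of light detection and of the clock and raised others. OPN4-1, a melanopsin (ENSGALG00000041662, chromosome 4, 37518259 to 37532248), fell by 0.79 ± 0.14, from 105 ± 17.4 to 60.9 ± 5.58 CPM (adjusted p = 0.00141). DUSP6, a phosphatase of ERK kinases, rose from 52.8 ± 5.4 to 86.3 ± 11 CPM (0.71 ± 0.11, adjusted p = 0.000355). Both calls held without any single library, with no overlap between the 4 and 4 libraries. The cone channel subunit CNGA3 fell by 0.78 ± 0.15 to 106 ± 12.4 CPM (adjusted p = 0.00837; 0.069 at most, without FDM libraries 2 or 4). TPH1, an enzyme of serotonin and melatonin synthesis, rose from 20.7 ± 12.4 to 56.1 ± 12.3 CPM (1.44 ± 0.28, adjusted p = 0.00824; 0.0764 at most, without FDM libraries 2, 3 or 4). The clock gene PER3 (ENSGALG00000000573, chromosome 21, 272583 to 291803) fell by 1.59 ± 0.36 to 62 ± 24.6 CPM (adjusted p = 0.0232, up to 0.111 without FDM libraries 2, 3 or 4 or ADTN libraries 1, 2 or 3), with overlap between the groups.

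With ADTN 66 genes rose and 53 fell at 4 h. Phototransduction genes were lower as a list, with PDE6B, CNGA3, GUCA1C and GRK7 of 34 past the threshold (5 up and 11 down adjusted over the list alone, adjusted p = 2.05e-05, or 0.518 with an estimated correlation). Of 29 clock genes TPH1 rose and PER2, PER3 and OPN4-1 fell (5 up and 6 down adjusted over the list alone; list adjusted p = 0.669). The FDM libraries differed among themselves in these genes: library 1 held 83 CPM of PER3 and 39.1 of TPH1, near the untreated means of 101 and 39.3, and libraries 2 to 4 held 213 to 231 and 12.4 to 16.6. TGFB2 and TGFBI rose among 20 BMP and TGF-beta genes (4 adjusted over the list alone, adjusted p = 0.000619, adjusted p = 0.31 with an estimated correlation). Rises also included 6 of 27 cytokine and NF-kB genes (12 adjusted over the list alone, adjusted p = 1.24e-07, adjusted p = 0.222 with an estimated correlation), 3 of 29 interferon-stimulated genes (19 adjusted over the list alone, adjusted p = 7.99e-16, adjusted p = 0.182 with an estimated correlation) and 2 of 34 immediate early genes (5 adjusted over the list alone, adjusted p = 1.2e-05, adjusted p = 0.222 with an estimated correlation). Blood vessel genes were higher as a list with 0 of 22 past the threshold (5 adjusted over the list alone, adjusted p = 1.19e-07, adjusted p = 0.408 with an estimated correlation); the vessel score was 3.32 ± 0.755 with ADTN and 1.4 ± 0.833 in FDM. The count of 119 was 496, 8, 27 and 8 without FDM libraries 1 to 4, and 22, 24, 30 and 490 without ADTN libraries 1 to 4. With ADTN libraries 1 to 3 and FDM library 1 high in small RNAs, it was 22 with the batch as a term, 11 with the vessel score and 58 with total count as a covariate.

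TPMPA, an antagonist of GABA-C receptors, was compared with FDM to find transcripts that change with its injection. At 4 h it raised genes of neuronal activity. FOS rose from 8.93 ± 1.72 to 85.9 ± 84 CPM (log2 3.25 ± 0.4, adjusted p = 4.92e-06) and NR4A1, a nuclear receptor induced by activity, from 7.4 ± 2.47 to 25.7 ± 12.3 (1.77 ± 0.24, adjusted p = 1.82e-05). EGR1 rose to 154 ± 175 CPM (2.82 ± 0.45, adjusted p = 0.00027), with 415 CPM in library 4 and 49.7 to 89.5 in the others. UTS2B rose from 3.63 ± 0.83 to 20.3 ± 12.2 CPM (2.49 ± 0.34, adjusted p = 1.82e-05) and VIP to 48.5 ± 12.9 (1.52 ± 0.23, adjusted p = 0.000126). These 5 calls held without any single library, with no overlap between the 4 and 4 libraries.

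TPMPA raised 65 genes at 4 h and lowered 9. Of 34 immediate early genes 10 rose (18 up and 1 down adjusted over the list alone, adjusted p = 3.02e-16, adjusted p = 0.00723 with an estimated correlation). VIP and UTS2B rose among 20 growth-related peptides (6 up and 1 down adjusted over the list alone, adjusted p = 5.79e-05, adjusted p = 0.0823 with an estimated correlation). GFAP, SOX2, SOX9 and STAT3 rose among 28 glial genes (6 adjusted over the list alone, adjusted p = 0.0206, adjusted p = 0.516 with an estimated correlation), each call lost without FDM libraries 2, 3 or 4 and without at least 1 TPMPA library (adjusted p up to 0.148, 0.132, 0.185 and 0.125). STAT3 was the 1 cytokine and NF-kB gene of 27 that rose (7 adjusted over the list alone, adjusted p = 0.000204, or 0.408 with an estimated correlation). Ribosomal proteins were lower as a list with 0 of 62 past the threshold (adjusted p = 2.84e-13, or 0.594 with an estimated correlation), and phototransduction genes with 0 of 34 (1 up and 7 down adjusted over the list alone, adjusted p = 0.00038, or 0.594 with an estimated correlation). The count of 74 was 418, 25, 31 and 23 without FDM libraries 1 to 4 and 42 without TPMPA library 3. It was 109 with the small-RNA batch as a term, 430 within the low libraries, 88 with the vessel score and 34 with total count as a covariate.

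At 4 h, 13 genes rose with all 4 drugs against FDM and none fell with all 4. Without FDM library 2 or 4 ADTN called 8 genes, so at most 8 of 13 held. The 13 included SDC1 (mean log2 change 4.07), IFITM5 (1.84), SPRY2, an inhibitor of receptor tyrosine kinase signalling (1.09), STAT3 (1.07), GFAP, FOS and the nucleotide receptor P2RY2. At an unadjusted p under 0.05, 250 genes went the same way with all 4 drugs, against a mean of 31.9 and at most 42 in simulated unchanged groups that shared the FDM libraries. The simulation (either time) was not checked for states real libraries share, such as vessel content, and may set too low a limit. Against untreated retina, 9 of the 13 were past the threshold for the mean of the injected groups, not FOS, PXDNL, TNS1 and ENSGALG00000011865 (a test chosen after the genes were known). At 24 h, 13, 13, 13 and 12 of the 13 had positive changes with atropine, pirenzepine, ADTN and TPMPA, and 3, 9, 1 and 0 were past the threshold; no gene was past it with all 4 drugs by edgeR, while 74 had unadjusted p under 0.05 with all 4 (simulated mean 27, at most 34) and DESeq2 called 3.

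**Figure D2:**
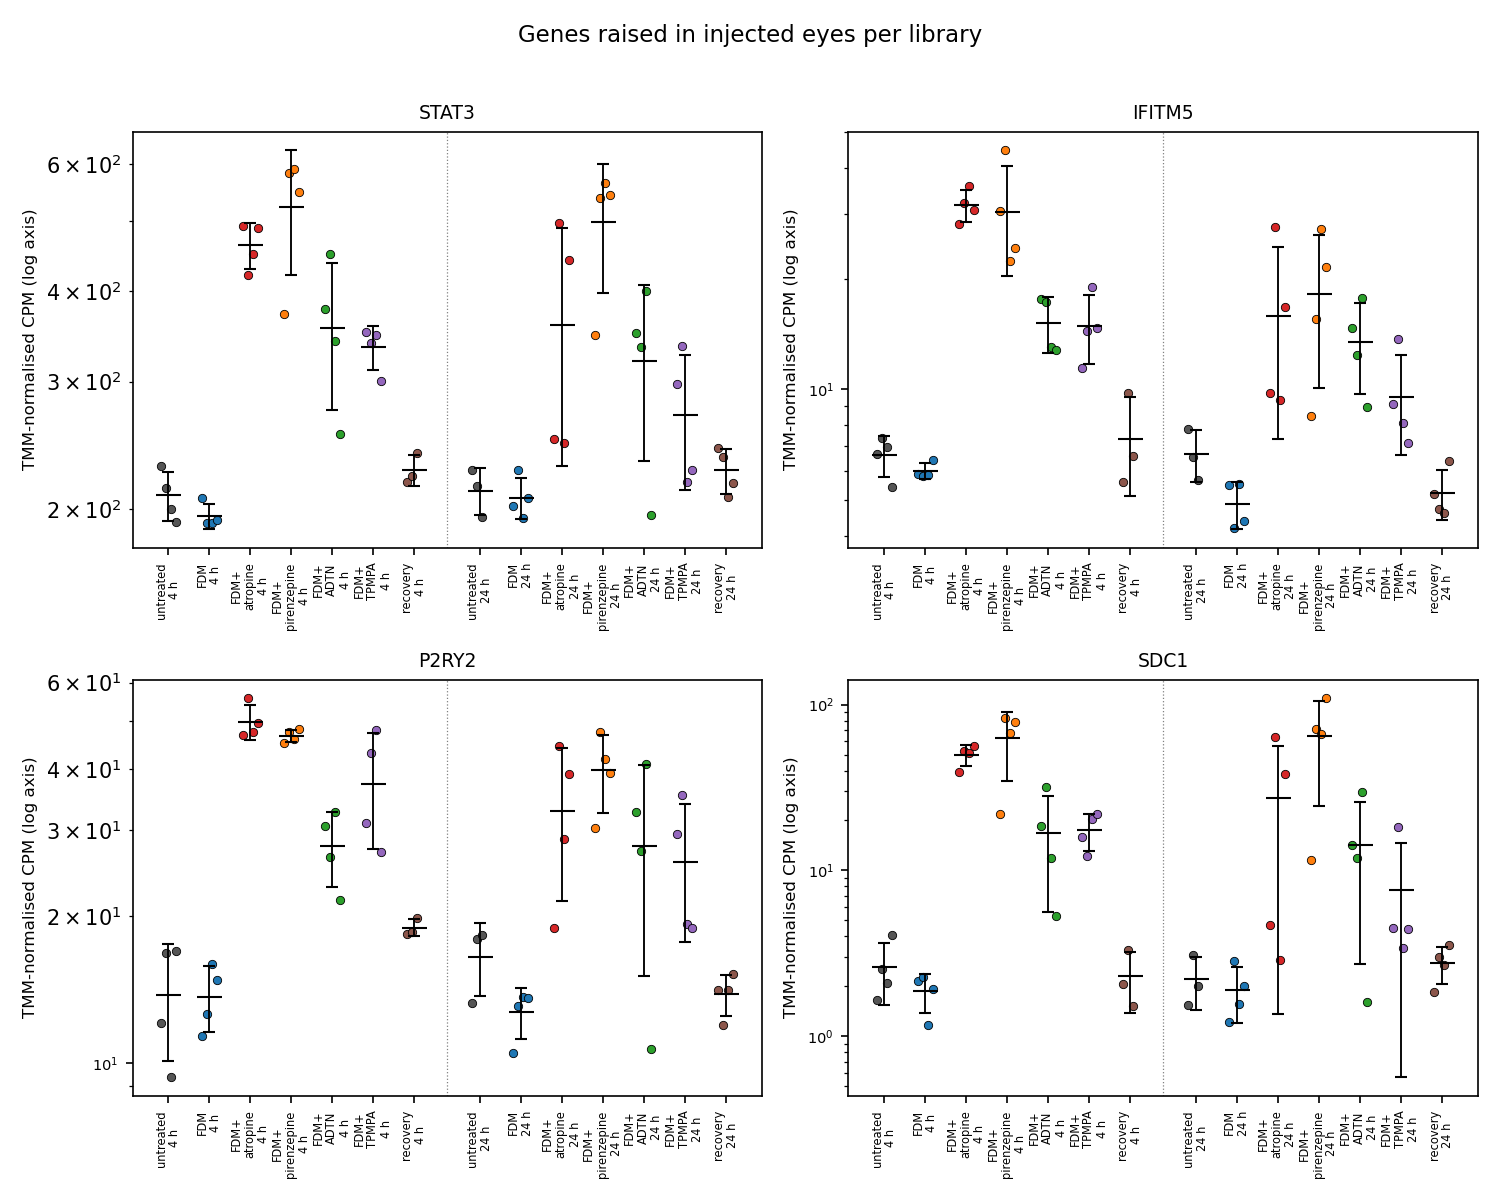
STAT3, IFITM5, P2RY2 and SDC1 in each of the 14 groups. Each point is a library, the vertical axis is TMM-normalised CPM on a log scale, dashes are means and bars are SD; STAT3 averages 463 CPM with atropine and 524 with pirenzepine at 4 h, against 196 in FDM.

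Whether the drugs moved genes back toward untreated levels was examined by correlating, across genes (which are not independent replicates), each drug change with the FDM change. At 4 h Pearson r was -0.51 for atropine, -0.384 for pirenzepine, -0.546 for ADTN and -0.53 for TPMPA. Both changes share the FDM libraries, and simulated unchanged groups gave -0.528, -0.524, -0.525 and -0.522. With the FDM libraries split so that none was shared, r was -0.104, -0.00927, -0.169 and -0.0835. At 24 h r was -0.568, -0.457, -0.477 and -0.757, simulated groups gave -0.461, -0.452, -0.46 and -0.45, and split libraries gave -0.304, -0.216, -0.181 and -0.485. FDM at 24 h also stood apart in vessel score (3.03, against 0.531 in untreated retina and 1.07 with TPMPA), and 3 of its 4 libraries were high in small RNAs, against 1 of 3 and 0 of 4. Of the 27 genes that fell in FDM at 4 h, 26, 26, 22 and 25 had the opposite sign with atropine, pirenzepine, ADTN and TPMPA, and 1, 6, 3 and 9 were past the threshold, again against the same FDM libraries.

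Recovery was compared with untreated retina to describe the eye once clear vision returned after 3 days of diffuser wear. At 4 h 6 entries were higher and none lower. TPM1, a tropomyosin of contractile and connective cells (ENSGALG00000003521, chromosome 10, 4105423 to 4124079), stood at 86.7 ± 61.6 CPM (n = 3) against 42.3 ± 0.77 (log2 1.03 ± 0.19, adjusted p = 0.0438), with another entry of its identifier also called. ALDH1A2, an enzyme of retinoic acid synthesis (ENSGALG00000004270, chromosome 10, 7045146 to 7099324), stood at 41.5 ± 59.1 against 6.85 ± 1.8 CPM (2.60 ± 0.54, adjusted p = 0.0469). The others, named after their values were seen, were FHL5 (3.27 ± 0.65), CLEC3B (4.74 ± 0.96) and ENSGALG00000040355 (3.53 ± 0.73). Recovery library 2 also stood apart in markers of other tissue: 296 CPM of the smooth muscle actin ACTA2 against 3.91 and 3.63, a connective tissue score of 4.58 against 2.56 and 2.68, and a vessel score of 4.89 against 0.477 and 1.25. EGR1 stood at 116 ± 12.3 CPM against 55.6 ± 12.8 (adjusted p = 0.586). Connective tissue genes were higher as a list with 0 of 22 past the threshold (6 adjusted over the list alone, adjusted p = 8.58e-06, adjusted p = 0.362 with an estimated correlation). TPM1 and ALDH1A2 were lost without any of untreated libraries 1 to 3 or recovery library 2 (adjusted p up to 1), and the count of 6 was 0 without any of untreated libraries 1 to 3 or recovery library 2, 20 without untreated library 4, and 32 and 51 without recovery libraries 1 and 3. It was 25 with the small-RNA batch as a term, 0 within the low libraries, 2 with the vessel score and 0 without untreated libraries 1 and 3 together.

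Against FDM, recovery at 4 h showed several activity genes at higher levels. FOS stood at 44.7 ± 6.81 CPM (n = 3) against 8.93 ± 1.72 (log2 2.32 ± 0.41, adjusted p = 0.00326) and DUSP4 at 16.7 ± 1.4 against 5.01 ± 1.28 (1.72 ± 0.25, adjusted p = 0.000189), with no overlap between the 3 and 4 libraries and no single library deciding either call. EGR1 rose to 116 ± 12.3 CPM (2.42 ± 0.46, adjusted p = 0.00824; 0.0524 without FDM library 3). BMP2, a growth factor of the eye wall (ENSGALG00000029301, chromosome 3, 15110369 to 15113622), rose to 41.1 ± 27.7 CPM (3.18 ± 0.64, adjusted p = 0.0117; up to 0.176 without FDM libraries 2, 3 or 4 or recovery library 2). In all 49 genes rose and 6 fell, with 6 of 34 immediate early genes higher (14 adjusted over the list alone). The count of 55 was 17, 9 and 11 without FDM libraries 2 to 4 and 15 without recovery library 2. It was 74 with the small-RNA batch as a term, 51 within the low libraries and 22 with the vessel score.

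At 24 h the comparison of FDM with untreated retina (n = 3) called no gene by edgeR (smallest adjusted p = 0.0952). Unadjusted p fell under 0.05 for 1136 genes; DESeq2 called 28 genes and limma voom 0. VIP stood at 17.1 ± 3.3 CPM against 34.5 ± 0.718 (adjusted p = 0.303), UTS2B at 3.97 ± 0.634 against 8.13 ± 1.31 (adjusted p = 0.576) and EGR1 at 28.1 ± 8.79 against 47.5 ± 7.16 (adjusted p = 0.73). For each of the 3 every FDM library lay below every untreated library. Growth-related peptides were lower as a list with 0 of 20 past the threshold (3 adjusted over the list alone, adjusted p = 0.00508, adjusted p = 0.334 with an estimated correlation). Blood vessel genes were higher as a list with 0 of 22 past it (13 adjusted over the list alone; median log2 change 2.74, adjusted p = 6.88e-11, adjusted p = 0.343 with an estimated correlation), with vessel scores of 3.03 ± 0.772 in FDM and 0.531 ± 0.0511 in untreated retina. Without FDM library 1, 2 or 3 the count was 1. It was 89 with only the FDM and untreated groups in the fit, 0 with the small-RNA batch as a term and 0 with the vessel score; FDM libraries 1 to 3 and untreated library 1 were high in small RNAs, which left too few untreated or FDM libraries for a fit within either class.

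Atropine at 24 h, 4 h after a repeat injection, raised 15 genes and lowered none. IFITM5 rose from 4.9 ± 0.71 to 15.9 ± 8.52 CPM (log2 1.69 ± 0.28, adjusted p = 0.00407; 0.0967 without atropine library 2). P2RY2 (ENSGALG00000042317, chromosome 1, 195388851 to 195390862) rose from 12.7 ± 1.53 to 32.8 ± 11.3 CPM (1.36 ± 0.25, adjusted p = 0.00884; up to 0.126 without FDM libraries 1 or 3 or atropine libraries 2 or 4). SDC1 rose from 1.91 ± 0.705 to 27.2 ± 29 CPM (3.83 ± 0.76) and SOCS3 from 0.961 ± 0.524 to 22.6 ± 25.2 (4.53 ± 0.9), with adjusted p = 0.0223 each and no overlap between the 4 and 4 libraries. Libraries 2 and 4 held 63.4 and 37.9 CPM of SDC1 and 55.8 and 28.3 of SOCS3, and libraries 1 and 3 held 4.67 and 2.88 of SDC1 and 3.47 and 2.69 of SOCS3. Both were lost without FDM libraries 1, 2 or 3 or atropine libraries 2 or 4 (adjusted p up to 0.249). VIP differed little, at 19.4 ± 4.48 against 17.1 ± 3.3 CPM (adjusted p = 0.76). SOCS3 was the 1 cytokine and NF-kB gene of 27 that rose (6 adjusted over the list alone, adjusted p = 2.38e-05, adjusted p = 0.362 with an estimated correlation). The count of 15 was 1, 5, 1 and 313 without FDM libraries 1 to 4, and 50, 0, 41 and 1 without atropine libraries 1 to 4. It was 3 with the small-RNA batch as a term and 18 with the vessel score, 0 with only the groups compared in the fit, 112 by DESeq2 and 0 by limma voom.

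Pirenzepine at 24 h, 4 h after a repeat injection, raised several activity genes and growth-related peptides. UTS2B rose from 3.97 ± 0.634 to 18.4 ± 5.41 CPM (log2 2.21 ± 0.33, adjusted p = 5.85e-05) and VIP from 17.1 ± 3.3 to 55.3 ± 18 (1.70 ± 0.23, adjusted p = 4.84e-05). CRH, corticotropin-releasing hormone, rose from 0.361 ± 0.182 to 4.14 ± 1.04 CPM (3.51 ± 0.63, adjusted p = 0.000494) and FOS from 13 ± 1.48 to 62.6 ± 24.2 (2.27 ± 0.38, adjusted p = 0.000225). STAT3 rose to 499 ± 101 CPM (1.27 ± 0.18, adjusted p = 4.84e-05), and CYP26A1, an enzyme that degrades retinoic acid, fell by 1.57 ± 0.31 to 3.51 ± 1.07 CPM (adjusted p = 0.00184). These 6 calls held without any single library, with no overlap between the 4 and 4 libraries.

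In all 194 genes rose and 63 fell with pirenzepine at 24 h. Of 20 growth-related peptides 5 rose (8 adjusted over the list alone, adjusted p = 3.58e-08, adjusted p = 0.00723 with an estimated correlation), and of 34 immediate early genes 6 rose (11 up and 2 down adjusted over the list alone, adjusted p = 2.13e-06, adjusted p = 0.182 with an estimated correlation). Of 28 glial genes 5 rose (11 adjusted over the list alone, adjusted p = 1.72e-07, adjusted p = 0.0823 with an estimated correlation), and of 27 cytokine and NF-kB genes 6 (10 adjusted over the list alone, adjusted p = 2.52e-09, adjusted p = 0.129 with an estimated correlation). Interferon-stimulated genes rose in 3 of 29 (7 adjusted over the list alone, adjusted p = 1.75e-06, adjusted p = 0.477 with an estimated correlation). CYP26A1 and CYP1B1 fell among 19 retinoic acid genes (adjusted p = 0.00405, adjusted p = 0.362 with an estimated correlation). The count of 257 was 170 and 162 without FDM libraries 1 and 2, and 452, 153 and 168 without pirenzepine libraries 1, 2 and 4. It was 307 with the small-RNA batch as a term, 37 within the high small-RNA libraries (25 of them among the 257) and 329 with the vessel score.

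ADTN at 24 h raised 2 genes and lowered 4. CADPS2, which primes dense-core vesicles (ENSGALG00000008926, chromosome 1, 22528298 to 22829235), fell by 0.78 ± 0.14, from 16.7 ± 2.47 to 9.69 ± 1.49 CPM (adjusted p = 0.0242; up to 0.114 without FDM library 3 or ADTN library 2). IFITM5 rose from 4.9 ± 0.71 to 13.4 ± 3.71 CPM (1.46 ± 0.28, adjusted p = 0.0277; up to 0.131 without any of FDM libraries 1 to 4 or ADTN libraries 1 to 3). TMEM132D, CORIN and FAM83B fell and ENSGALG00000004604, named after its values were seen, was higher, each with adjusted p = 0.0277. Without a single library the adjusted p of the first 3 reached 0.137 (FDM 1, 3 or 4 or ADTN 2, 3 or 4), 0.109 (any of the 8) and 0.218. Of the 5 named genes none overlapped between the 4 and 4 libraries. VIP and UTS2B stood at 15.7 ± 3.1 and 2.71 ± 0.833 CPM (adjusted p = 0.928 and 0.724). The count of 6 was 2, 3, 1 and 3 without FDM libraries 1 to 4, and 2, 0, 1 and 15 without ADTN libraries 1 to 4. It was 12 with the small-RNA batch as a term, 63 within the high small-RNA libraries, 15 with the vessel score, 0 with only the groups compared in the fit and 24 by DESeq2.

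TPMPA at 24 h called no gene by edgeR (smallest adjusted p = 0.0728). Unadjusted p fell under 0.05 for 1844 genes; DESeq2 called 41 genes and limma voom 0. UTS2B stood at 11.4 ± 2.8 CPM against 3.97 ± 0.634 (log2 1.52 ± 0.33, adjusted p = 0.0728) and VIP at 34.3 ± 7.6 against 17.1 ± 3.3 (1.01 ± 0.23, adjusted p = 0.0843), both without overlap between the 4 and 4 libraries. Growth-related peptides were higher as a list (0 of 20 past the threshold, 3 adjusted over the list alone, adjusted p = 0.000154, adjusted p = 0.0948 with an estimated correlation). Blood vessel genes were lower as a list (0 of 22, 5 adjusted over the list alone, adjusted p = 2.4e-06, or 0.472 with an estimated correlation), with a vessel score of 1.07 ± 0.497 against 3.03 ± 0.772. Ribosomal proteins were higher (0 of 62, adjusted p = 7.29e-18, or 0.516 with an estimated correlation), at a mean total of 12.3 against 16 M. The count of genes past the threshold was 2 without FDM library 4 and 1 without TPMPA library 2. With the small-RNA batch as a term it was 2, with the vessel score 0, and with only the FDM and TPMPA groups in the fit 276; 3 of 4 FDM libraries were high and all TPMPA libraries at 24 h were low in small RNAs.

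Recovery at 24 h differed from untreated retina (n = 3) in some genes of the daily clock, among others. ARNTL, the partner of CLOCK in the core loop (ENSGALG00000005378, chromosome 5, 7560411 to 7582957), fell by 1.5 ± 0.19, from 191 ± 9.14 to 67.2 ± 12.4 CPM (adjusted p = 6.56e-06). NFIL3, a repressor of the same system (ENSGALG00000015209, chromosome Z, 44346752 to 44358514), fell by 1.5 ± 0.19, from 174 ± 20.1 to 61.2 ± 11.3 CPM (adjusted p = 7.86e-06). PPEF2, a photoreceptor phosphatase, fell by 1.01 ± 0.16 to 60.5 ± 7.75 CPM (adjusted p = 0.000424), and the metabolic genes G0S2, an inhibitor of lipolysis, and NDRG1 fell by 1.51 ± 0.26 and 0.89 ± 0.15 (adjusted p = 0.000785 each). SKOR1, a transcriptional corepressor, rose from 22.9 ± 5.91 to 55.1 ± 10.5 CPM (1.27 ± 0.22, adjusted p = 0.000785). These 6 calls held without any single library, and the 4 recovery libraries did not overlap the 3 untreated ones.

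At 24 h of recovery 34 genes rose and 69 fell. Of 29 clock and melatonin genes 5 fell and 2 rose (8 and 6 adjusted over the list alone; list adjusted p = 0.0669, since members went both ways). PER3 stood at 275 against 102 CPM (log2 1.42, adjusted p = 0.0686). GABRR3, a subunit of GABA-C receptors, and the glycine receptor subunit GLRA3 fell (lost without single libraries, adjusted p up to 0.11 and 0.249) among 32 genes of inhibitory transmission (4 adjusted over the list alone, adjusted p = 0.000185, adjusted p = 0.363 with an estimated correlation). Blood vessel genes were higher as a list with 0 of 22 past the threshold (19 adjusted over the list alone; median log2 change 3.56, adjusted p = 1.92e-13, adjusted p = 0.222 with an estimated correlation), and interferon-stimulated genes with 0 of 29 (3 adjusted over the list alone, adjusted p = 9.2e-08, adjusted p = 0.416 with an estimated correlation). EGR1 stood at 118 ± 17.2 against 47.5 ± 7.16 CPM (adjusted p = 0.185). The count of 103 was 64, 24 and 36 without untreated libraries 1 to 3 and 40 and 28 without recovery libraries 1 and 2. It was 371 with only the groups compared in the fit, 325 by DESeq2, 140 with the small-RNA batch as a term and 46 with the vessel score, which averaged 3.66 ± 0.512 in recovery and 0.531 ± 0.0511 in untreated retina; the high small-RNA libraries were recovery 1 to 3 and untreated 1.

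**Figure D3:**
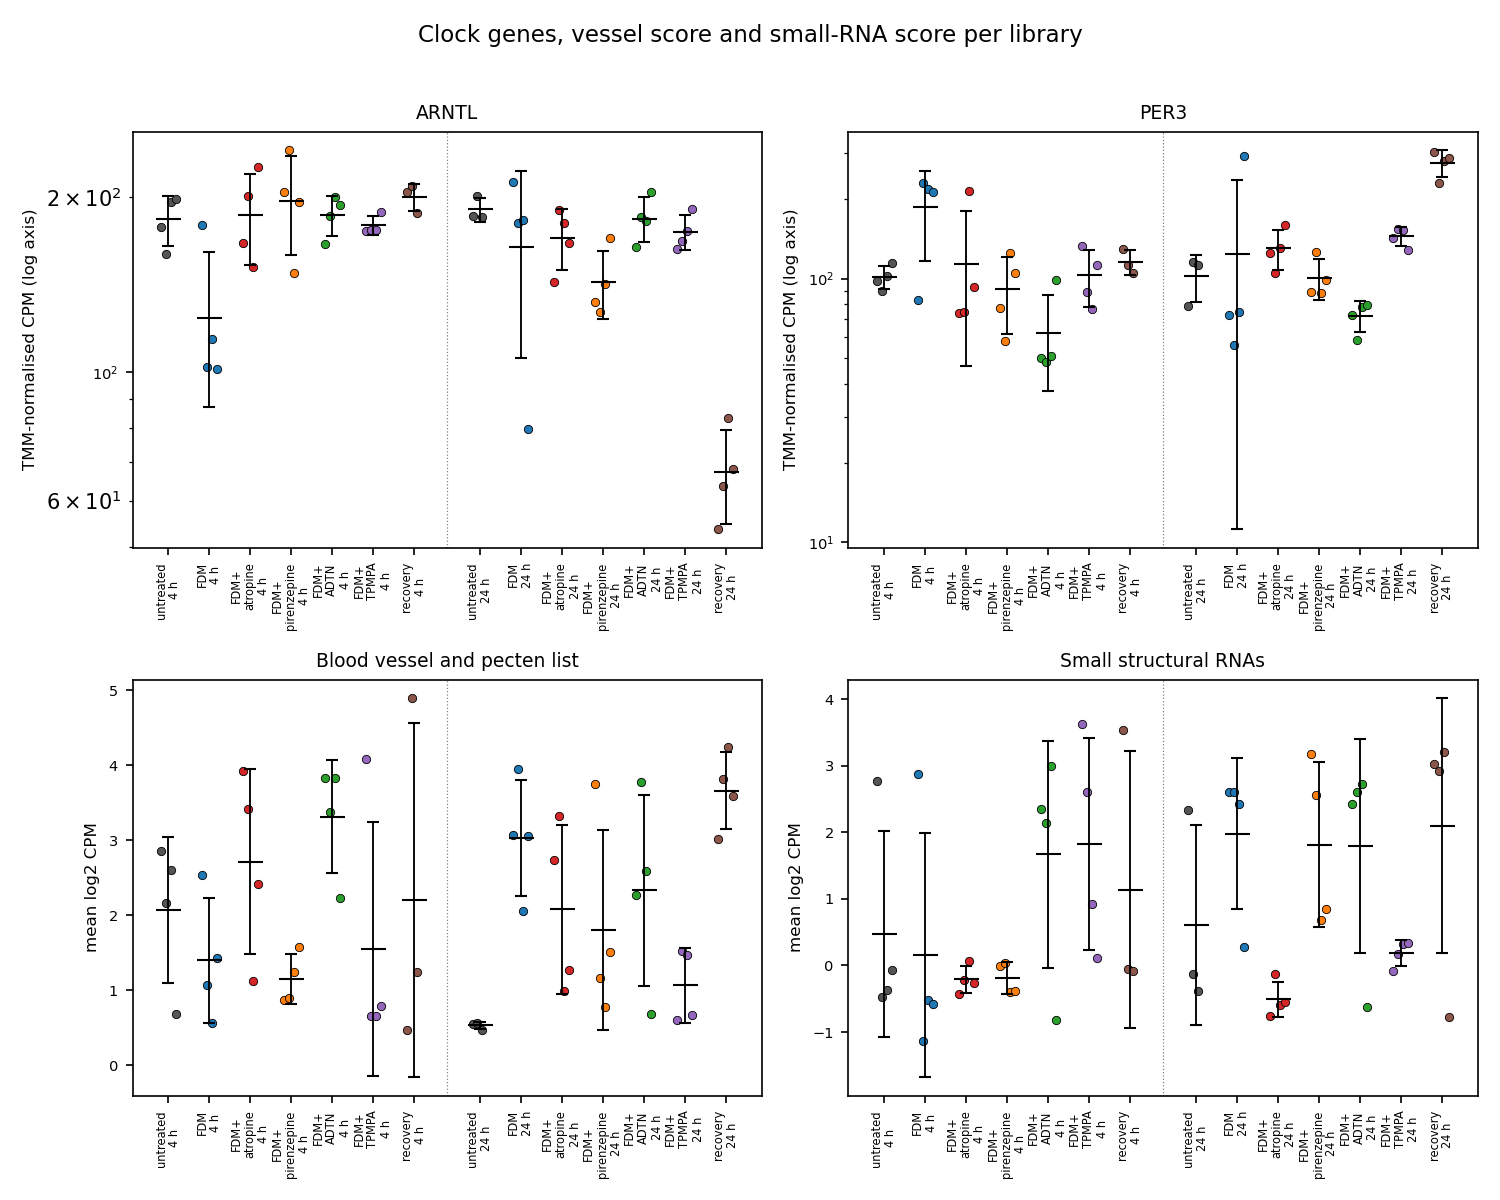
ARNTL and PER3 (TMM-normalised CPM, log axis), the blood vessel and pecten score and the small-RNA score (mean log2 CPM) in each of the 14 groups. Points are libraries, dashes are means and bars are SD; recovery at 24 h averages 67.2 CPM of ARNTL against 191 in untreated retina, and a vessel score of 3.66 against 0.531.

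Against FDM at 24 h, recovery raised 72 genes and lowered 112. KIF15, a mitotic kinesin, fell by 2.35 ± 0.48 to 1.09 ± 0.259 CPM (adjusted p = 0.00584), TPH1 by 1.47 ± 0.28 to 11.8 ± 1.66 (adjusted p = 0.0033) and STXBP4 by 0.85 ± 0.15 to 49.3 ± 5.92 (adjusted p = 0.00121). PLXDC1 rose by 1.01 ± 0.21 to 14.3 ± 1.61 CPM (adjusted p = 0.00545). None of these 4 overlapped between the 4 and 4 libraries, and their calls held without any single library. EGR1 rose from 28.1 ± 8.79 to 118 ± 17.2 CPM (2.07 ± 0.43, adjusted p = 0.00729; 0.0626 without FDM library 3). Of 34 immediate early genes 2 rose (13 up and 1 down adjusted over the list alone), and of 29 clock genes 3 rose and 5 fell (7 and 8 adjusted over the list alone). The count of 184 was 66, 81, 46 and 351 without FDM libraries 1 to 4, and 87 and 76 without recovery libraries 1 and 2. It was 298 with the small-RNA batch as a term, 337 within the high libraries and 229 with the vessel score.

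Untreated retinas of the 2 ages differed in 2 genes, both lower at 24 h (n = 3) than at 4 h. CHAC1 fell by 4.77 ± 0.85, from 40.4 ± 40.2 to 1.48 ± 0.698 CPM (adjusted p = 0.0222; up to 0.356 without untreated 4 h libraries 1 or 3 or any 24 h library). MTHFD2, a mitochondrial enzyme of folate metabolism (ENSGALG00000034344, chromosome 22, 2886809 to 2893328) named after its values were seen, fell by 1.72 ± 0.33, from 90.1 ± 60.5 to 27.3 ± 4.92 CPM (adjusted p = 0.0421). The count was 0, 9, 0 and 22 without untreated 4 h libraries 1 to 4, and 0 without any of the 3 at 24 h. It was 1 with the small-RNA batch as a term, 0 within the low libraries and 0 with the vessel score.

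The change between 4 h and 24 h itself differed for 10 genes in recovery and for 0 in the other contrasts by edgeR. In recovery, the change of ARNTL was 1.63 ± 0.26 lower on the log2 scale at 24 h than at 4 h and that of NFIL3 1.47 ± 0.27 lower, so that their falls belonged to the later time. Unadjusted p fell under 0.05 for 1429 genes in FDM, 1276 with atropine, 951 with pirenzepine, 1105 with ADTN, 2301 with TPMPA and 1069 in recovery; DESeq2 called 21, 2, 5, 2, 26 and 65, and limma voom 0, 0, 0, 0, 0 and 5. For FDM the count was 2 and 9 without untreated 4 h libraries 2 and 4; for pirenzepine 1 without its 4 h library 4 and 9 without FDM 24 h library 4; for ADTN 1 without FDM 4 h library 1 and 1 without ADTN 4 h library 4. With TPMPA it was 11, 2 and 12 without FDM 4 h library 1, TPMPA 4 h library 1 and FDM 24 h library 4. For recovery it was 5, 6 and 19 without untreated 4 h libraries 1, 3 and 4, 3 and 5 without recovery 4 h libraries 1 and 2, 6 and 5 without untreated 24 h libraries 1 and 2, and 5, 6 and 6 without recovery 24 h libraries 1, 3 and 4; with the small-RNA batch as a term it was 10 and with the vessel score 6.

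The remaining lists gave smaller or mixed results. Of 19 dopamine genes and 12 lens genes none was past the threshold in any main comparison by edgeR, and the list tests gave adjusted p of at least 0.124 and 0.343. Of 21 cholinergic genes BCHE fell with atropine at 4 h and SLC5A7, the choline transporter, rose with pirenzepine at 24 h, while the list was lower with ADTN at 4 h (adjusted p = 0.00472, adjusted p = 0.362 with an estimated correlation). Of 25 genes of pigment epithelium and melanocytes OCA2 rose with atropine at 4 h and with pirenzepine at both times, and the list was higher in recovery at 4 h (adjusted p = 0.000461, adjusted p = 0.613 with an estimated correlation), with a score of 5.37 in library 2, which stood apart in other tissue, and 4.46 and 4.42 in the others, against 3.92 to 4.57 in untreated retina. Of 33 hypoxia and glycolysis genes 3 rose with pirenzepine at 4 h (list adjusted p = 0.377), and NDRG1 fell in recovery at 24 h (list lower, adjusted p = 0.0205, adjusted p = 0.694 with an estimated correlation). Microglia and leukocyte genes were higher with ADTN at 4 h (0 of 29 past the threshold, 6 adjusted over the list alone, adjusted p = 0.00025, adjusted p = 0.543 with an estimated correlation). Cholesterol and lipid genes were higher in recovery at 4 h (0 of 26, adjusted p = 1.17e-06, adjusted p = 0.362 with an estimated correlation), as were genes of heat shock and folding (0 of 32, adjusted p = 0.0033, adjusted p = 0.509 with an estimated correlation).

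Lists of neuronal classes were lower in some drug groups. Bipolar cell genes were lower with ADTN at 4 h, where GRIK1 of 17 fell (adjusted p = 0.000665, adjusted p = 0.18 with an estimated correlation). With atropine at 24 h ganglion cell genes (0 of 19 past the threshold, adjusted p = 0.000185, adjusted p = 0.408 with an estimated correlation) and amacrine and horizontal cell genes (0 of 18, adjusted p = 0.000376, adjusted p = 0.362 with an estimated correlation) were lower. ENPP6, an enzyme of myelinating cells, fell with pirenzepine at 4 h by 0.89 ± 0.18 (adjusted p = 0.0021) and its list of 18 was lower (adjusted p = 0.000413, adjusted p = 0.408 with an estimated correlation). Red blood cell genes were higher in recovery at 24 h (0 of 9, adjusted p = 0.0342, adjusted p = 0.343 with an estimated correlation), as were ciliary body and iris genes (0 of 18, 5 adjusted over the list alone, adjusted p = 0.0162, adjusted p = 0.408 with an estimated correlation). Of 336 tests of lists 123 were past the threshold with the preset correlation and 3 with an estimated one: immediate early genes in FDM and with TPMPA at 4 h, and growth-related peptides with pirenzepine at 24 h.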

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

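Rules that single out a far sample or a difference between times were set before the data were examined. The tests of explanations in the last 3 paragraphs of this part were all chosen after the results were seen.

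In groups of 4 samples, the values of the followed genes, the named genes, total count and the vessel score were searched for a sample far from the other 3. Of 371 such group tests 32 found one, where chance alone gives about 19. Among the followed genes (CPM), the far samples were BMP2 with atropine at 4 h (34.7 in library 3, others 4.76 to 7.38), UTS2B with pirenzepine at 4 h (16.9 in library 3, others 6.53 to 8.2), TH with ADTN at 4 h (1.49 in library 2, others 3.42 to 3.78) and EGR1 with TPMPA at 4 h (415 in library 4, others 49.7 to 89.5). At 24 h they were TH in FDM (5.69 in library 4, others 2.73 to 3.2), EGR1 with pirenzepine (137 in library 3, others 71.2 to 78.9), NTS with pirenzepine (174 in library 4, others 131 to 136), BMP2 with ADTN (17.7 in library 4, others 4.5 to 5.88), NTS with ADTN (173 in library 4, others 99.7 to 109) and EGR1 with TPMPA (115 in library 2, others 41.7 to 49.8). The vessel score with TPMPA at 4 h was 4.08 in library 1 and 0.657 to 0.789 in the others. Total count was 24.8 M in atropine library 3 at 24 h (others 12.8 to 14.1) and 13.6 M in recovery library 1 at 24 h (others 16.2 to 16.6).

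Among the named genes, FDM libraries at 4 h held 7 of the far samples. Library 1 was far in PPP1R3C (22.2, others 11.8 to 13.1), PACAP (21, others 14.3 to 15), IRF1 (2.24, others 0.697 to 0.912) and TPH1 (39.1, others 12.4 to 16.6), library 2 in AOX1 (92, others 60.5 to 63.1) and BVES (30.1, others 26.1 to 26.5), and library 4 in IFITM5 (6.45, others 5.82 to 5.89). Pirenzepine library 1 at 4 h was far in GLDN (1.82, others 9.59 to 10), MATN3 (4.13, others 7.78 to 8.29), MYPN (12.7, others 6.73 to 7.64) and AHR1B (22.8, others 9.95 to 12). ADTN library 4 at 4 h was far in CNGA3 (124, others 98.1 to 100). In FDM at 24 h the far values were P2RY2 (10.5 in library 1, others 13.1 to 13.7), FER1L6 (4.92 in library 4, others 0.756 to 1.28), TMEM132D (120 in library 2, others 133 to 134) and STXBP4 (62.6 in library 4, others 95.7 to 99.2). With atropine at 24 h they were NLRX1 (46.2 in library 1, others 25.1 to 28) and FOSL2 (12.9 in library 2, others 5.83 to 6.45), and with pirenzepine at 24 h MCM3 (28.6 in library 4, others 14.6 to 15.6).

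Changes in recovery against untreated retina differed between the times for 10 genes, by a test of the difference itself (24 h minus 4 h, log2 ± SE). Lower at 24 h were the clock genes ARNTL (-1.63 ± 0.26, adjusted p = 0.0029) and NFIL3 (-1.47 ± 0.27, adjusted p = 0.0106), the photoreceptor phosphatase PPEF2 (-1.25 ± 0.22, adjusted p = 0.00925), IQGAP2 (-0.68 ± 0.13, adjusted p = 0.0112), ENSGALG00000014978 (-0.72 ± 0.14, adjusted p = 0.013) and ENSGALG00000011865 (-0.63 ± 0.13, adjusted p = 0.0382). Higher at 24 h were NR1D2 (0.64 ± 0.14, adjusted p = 0.0411), KIAA1522 (2.44 ± 0.53, adjusted p = 0.0491), CHAC1 (5.91 ± 1.1, adjusted p = 0.0106) and MTHFD2 (2.18 ± 0.45, adjusted p = 0.0382). For CHAC1 the changes were -2.80 at 4 h and 3.11 at 24 h, and the 4 h value rests on untreated libraries 1 and 3. Without single libraries the count of 10 ran from 3 to 19.

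In recovery at 24 h, 7 of 29 clock and melatonin genes were past the threshold, with ARNTL and NFIL3 lower and NR1D2 higher. The small-RNA batch as a term left all 7 calls and 0.994 of their median absolute change, which argues against it as the whole cause. Vessel content as a covariate left 1.11 of it, with a median of 0.76 before and 0.84 after (median SE 0.18 and 0.21), which argues against vessel content as the whole cause, although 4 of 7 calls were left because SE grew and OPN4 moved toward 0. Collection at another phase of the day needs members to move as they vary with ARNTL among the other 50 libraries. Over 28 members, not independent replicates, they did (r = 0.747, rho = 0.617, permutation p = 2e-05). A different phase at collection may account for the pattern, but any cause moving these members together, such as recovery, predicts the same. Times of day are not given in the sources.

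Blood vessel genes differed between groups, with scores of 3.66 in recovery, 3.03 in FDM and 0.531 in untreated retina at 24 h. VWF, a marker of endothelium chosen after its values were seen, averaged 56.5 ± 28.9 CPM in FDM, 65.6 ± 18.9 in recovery and 0.105 ± 0.182 in untreated retina. The small-RNA batch as the whole cause is argued against, since with the batch fitted beside the groups recovery still lay 2.81 ± 0.83 above untreated retina (3.13 without it); this comparison with 0 was chosen after 2 stricter bounds had left the batch open. Within groups lay 55% of the score's variation, a share not set against equal groups. Vessel or pecten tissue taken at dissection stays open. The batch as a part of the cause stays open, as high libraries lay 0.76 ± 0.38 above low ones with groups fitted; growth or leakage of vessels through treatment was not tested.

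The 13 genes higher with all 4 drugs at 4 h were compared with 3 explanations. Low values by chance in the shared FDM libraries are argued against for the 9 that were past the threshold for the injected groups against untreated retina, such as IFITM5 (log2 1.70, adjusted p = 2.83e-05), and stay open for the other 4, such as FOS (0.44, adjusted p = 0.753). Lower total counts of the FDM libraries are argued against as the whole cause: with total count as a covariate 0.958 of the median change was left (log2 1.55 before and 1.49 after, median SE 0.29 and 0.31). Of the 13 genes 6 stayed past the threshold in all 4 comparisons; a count of these calls, used before the share, had left this open. The injection itself, whatever the drug, stays open: at least 12 of 13 had positive changes in every injected group at 24 h, but these groups share the FDM libraries and a repeated drug predicts the same. Drug and injection cannot be told apart, since no group with vehicle was used here.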

How the results depend on the processing

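Alternatives were planned before the data were examined, except the small-RNA, vessel and total-count terms, the fits within small-RNA classes and the removal of untreated libraries 1 and 3, which were chosen after seeing the data. Of 281 calls of named genes (a gene counts once in each comparison) none reversed under any alternative, 44 stayed past it under every alternative run for them and 237 were lost under at least 1. RLE size factors moved no count by over 1.5 times. Comparisons below are drug groups against FDM and FDM or recovery against untreated retina unless stated. Except where the alternative itself removes libraries or genes, the cause was not tested.

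With DESeq2 the counts at 4 h were 63 (FDM), 313 (atropine), 507 (pirenzepine), 321 (ADTN), 194 (TPMPA), 32 (recovery), 96 (recovery against FDM) and 5 (atropine against pirenzepine). At 24 h they were 28 (FDM), 112 (atropine), 24 (ADTN), 41 (TPMPA), 325 (recovery), 345 (recovery against FDM) and 110 (atropine against pirenzepine), and 22 between untreated ages. Differences between times were 21 (FDM), 2 (atropine), 5 (pirenzepine), 2 (ADTN), 26 (TPMPA) and 65 (recovery). DESeq2 calls shared by all 4 drugs were 28 at 4 h and 3 at 24 h. By edgeR, unadjusted p under 0.05 in all 4 gave 250 and 74. With limma voom counts were 2 (FDM), 112 (atropine), 209 (pirenzepine), 65 (ADTN), 46 (TPMPA), 0 (recovery) and 13 (recovery against FDM) at 4 h, 0 (atropine at 24 h), 0 (untreated ages) and 5 (recovery between times).

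No filter gave 3 (recovery at 4 h), 20 (atropine against pirenzepine at 24 h), 1 (untreated ages) and 6 (recovery between times). Every transcript entry tested separately gave 19 (recovery at 4 h) and 1 (untreated ages). Only the groups compared in the fit gave 4 (FDM), 128 (pirenzepine), 32 (ADTN), 29 (TPMPA) and 11 (recovery against FDM) at 4 h, and at 24 h 89 (FDM), 0 (atropine), 101 (pirenzepine), 0 (ADTN), 276 (TPMPA), 371 (recovery), 26 (recovery against FDM) and 116 (atropine against pirenzepine), with 0 between untreated ages and 1 (TPMPA) and 61 (recovery) between times. Residuals of libraries with equal replicate numbers had a mean correlation of 0.0511 at 4 h (from -0.341 to 0.532) and 0.0505 at 24 h (from -0.21 to 0.426), against -0.0181 and -0.0174 for different numbers, and 12 and 13 of 27 libraries correlated best with their own number, a hint from the data only. With the replicate block counts were 270 (ADTN), 203 (TPMPA), 0 (recovery) and 31 (recovery against FDM) at 4 h, 2 (FDM), 112 (atropine), 15 (TPMPA), 285 (recovery) and 71 (atropine against pirenzepine) at 24 h, 0 between untreated ages, and 2 (TPMPA) and 17 (recovery) between times.

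Of the list tests 3 passed with an estimated correlation and 20 with fry, against 123. With the FDM libraries split, r between drug and FDM changes was -0.104, -0.00927, -0.169 and -0.0835 at 4 h and -0.304, -0.216, -0.181 and -0.485 at 24 h for atropine, pirenzepine, ADTN and TPMPA. Without the split and with only the genes changed in FDM at 4 h it was -0.535, -0.677, -0.35 and -0.239, where the choice of genes in the same FDM libraries builds in a negative relation. With untreated libraries split, r between FDM and recovery at 4 h was 0.0177.

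Total count as a covariate gave 8 (FDM), 58 (ADTN) and 34 (TPMPA) at 4 h, 2 (TPMPA at 24 h) and 1 (untreated ages). The high small-RNA libraries alone gave 37 (pirenzepine), 63 (ADTN) and 337 (recovery against FDM) at 24 h. The low ones gave 48 (FDM), 164 (pirenzepine), 430 (TPMPA) and 0 (recovery) at 4 h, 17 (atropine against pirenzepine at 24 h) and 0 (untreated ages). The batch as a term gave 22 (ADTN) and 25 (recovery) at 4 h, 3 (atropine), 12 (ADTN), 2 (TPMPA) and 298 (recovery against FDM) at 24 h and 1 (untreated ages). The vessel covariate gave 11 (ADTN), 2 (recovery) and 22 (recovery against FDM) at 4 h, 15 (ADTN) and 46 (recovery) at 24 h, 0 (untreated ages) and 6 (recovery between times). Without untreated libraries 1 and 3 FDM and recovery at 4 h gave 0 and 0. Classes that left a group under 2 libraries could not be fitted.

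Without single libraries counts at 4 h ran from 3 to 73 (FDM), 91 to 200 (atropine), 142 to 409 (pirenzepine), 8 to 496 (ADTN), 23 to 418 (TPMPA), 0 to 51 (recovery), 9 to 67 (recovery against FDM) and 0 to 4 (atropine against pirenzepine). At 24 h they ran from 0 to 1 (FDM), 0 to 313 (atropine), 153 to 452 (pirenzepine), 0 to 15 (ADTN), 0 to 2 (TPMPA), 24 to 104 (recovery), 46 to 351 (recovery against FDM) and 8 to 48 (atropine against pirenzepine), with 0 to 22 between untreated ages. Between times they ran from 0 to 9 (FDM), 0 to 0 (atropine), 0 to 9 (pirenzepine), 0 to 1 (ADTN), 0 to 12 (TPMPA) and 3 to 19 (recovery), and for list tests from 118 to 130. The report names the libraries behind many of these ranges, not all. At these depths the simulated data gave 65.7% of 1.5-fold changes at 4 h and 53.7% at 24 h, so changes of that size are often missed.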

Other observations

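Of the tests in this part, the counts of splits were planned before the data were examined; genes in the first 2 paragraphs were picked after their values were seen.

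Clock genes in FDM at 4 h lay in the direction later seen in recovery at 24 h, without passing the test. ARNTL averaged 124 CPM in FDM and 183 in untreated retina (log2 -0.56, adjusted p = 0.3), NFIL3 119 and 189 (-0.67, adjusted p = 0.15), and PER3 186 and 101 (0.88, adjusted p = 0.57). The means hide different states: FDM library 1 held 179 CPM of ARNTL and 83 of PER3, and libraries 2 to 4 held 101 to 114 and 213 to 231. In FDM at 24 h library 4 held 79.6 and 292, and libraries 1 to 3 held 181 to 213 and 55.9 to 74.4. In both groups the libraries with less ARNTL were the ones low in small RNAs. In the 5 other groups at 4 h ARNTL averaged 179 to 200 CPM. PER3 averaged 62 CPM with ADTN, below the 101 of untreated retina, and 91.5 to 116 with atropine, pirenzepine, TPMPA and in recovery.

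SDC1 and SOCS3 were highest with pirenzepine and next highest with atropine at both times, by group means, a ranking that was not tested across the 4 drugs. SDC1 averaged 62.6 CPM with pirenzepine, 49.8 with atropine, 17.6 with TPMPA and 16.8 with ADTN at 4 h, and 64.4, 27.2, 7.63 and 14.3 at 24 h, against 1.88 to 2.77 in untreated, FDM and recovery groups. SOCS3 averaged 32.4, 23.1, 11 and 12.3 CPM at 4 h and 48.5, 22.6, 5.33 and 10.7 at 24 h for the same drugs, and 0.781 to 3.96 in the groups without injection. Single libraries carry part of this ranking at 24 h. Atropine libraries 1 and 3 were low in both genes (values above), and ADTN library 4 held 1.61 CPM of SDC1 and 0.402 of SOCS3. FOS averaged 85.9 CPM with TPMPA at 4 h, a mean carried by library 4 (210, others 30.4, 36.5 and 67), and 40.4, 25.9 and 26 with pirenzepine, atropine and ADTN.

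Changes in FDM and in recovery, each against untreated retina, went together across genes with r = 0.37 at 4 h and 0.772 at 24 h. Both share the untreated libraries, simulated unchanged groups gave 0.451 and 0.578, and with untreated libraries split at 4 h r was 0.0177. At 24 h FDM and recovery also shared high vessel scores (3.03 and 3.66, against 0.531 in untreated retina), and 3 of 4 libraries of each were high in small RNAs, against 1 of 3.

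How often a random grouping gives as many genes was counted with other splits of the same libraries, fitted with only the groups compared. The real split alone reached its count, 1 of 35, for atropine at 4 h (real 214, highest other 162), pirenzepine at 4 h (128, 41) and 24 h (101, 40), TPMPA at 24 h (276, 2), recovery at 24 h (371, 201), recovery against FDM at 24 h (26, 2) and atropine against pirenzepine at 24 h (116, 78). This is the smallest share the splits can give. It was not adjusted for the number of comparisons, so it does not by itself exclude chance. The highest other split for recovery at 24 h parted the libraries exactly by the small-RNA batch; in the fit of all groups the count was 103, and 140 with the batch as a term. For TPMPA at 24 h the real split itself nearly followed the batch (3 of 4 FDM libraries high, all TPMPA libraries low). In the fit of all groups the count was 0, and 2 with the batch as a term. No batch term was added to the fit of these groups alone, so the batch stays open for the 276.

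In the other comparisons further splits reached the real count as well. As many genes came from 2 splits for FDM at 4 h (real 4, highest other 1341), ADTN at 4 h (32, 2320), FDM at 24 h (89, 877) and recovery against FDM at 4 h (11, 55), and from 3 splits for TPMPA at 4 h (29, 208) and recovery at 4 h (4, 16). A real count of 0 is reached by all 35 splits whatever the data, so the splits decide nothing for atropine at 24 h (highest other 628), ADTN at 24 h (2), atropine against pirenzepine at 4 h (1) and untreated retina at both ages (108). Where the highest split lay several times above the real count it points to a structure of the samples. For ADTN at 4 h and FDM at 24 h that split was the small-RNA batch itself. In the fit of all groups the counts were 119 and 0, and 22 and 0 with the batch as a term. For FDM at 4 h it set untreated libraries 1 to 3 with FDM library 1, and for atropine at 24 h FDM libraries 1 to 3 with atropine library 1.

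For the differences between times, 100 splits were drawn. For FDM (real 0, highest other 3280), atropine (0, 807), pirenzepine (0, 278) and ADTN (0, 3) all 100 reach the real count of 0 whatever the data, which decides nothing. As many genes came from 6 of 100 for TPMPA (1, 1538) and 5 of 100 for recovery (61, 247), so chance cannot be excluded for these. The highest split for FDM followed the small-RNA batch of the 24 h libraries, and with the batch as a term the count for recovery was 10.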
